A study of Mus musculus with 25 samples.

How the data were processed

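Hippocampal RNA was sequenced from wild-type and Scn1a+/- mice at postnatal day 14 (P14) and 24 (P24) on the 129S6/SvEvTac background (here 129S6) and in [129S6/SvEvTac x C57BL/6]F1 animals (here F1). Per the labels' protocols, hippocampi were flash frozen, RNA was extracted with TRIzol, and libraries were made with a kit that does not mark strand, TruSeq RNA Library Preparation Kit v2. Each library was a pool of animals, and per the labels the pools of the seizure group held fewer mice than the other pools. The 25 libraries fall into 9 groups, taken from titles and characteristics. Nothing in the labels says how separate the pools of a group were in litter or day, so p-values measure the spread between these pools. The titles number the libraries over the whole series, and these numbers pair no libraries.

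The authors deposited 1 file of raw gene counts per library, whole numbers for 24421 gene symbols, with 0 lines that name no gene. The submitters' processing notes name CASAVA, TopHat2 2.1.0, HTSeq 0.6.1p1 and the genome build mm10. The gene annotation and the strand setting of the counting are not given in the sources used here, so counts of overlapping genes and of antisense partners cannot be told apart. The authors also deposited 1 table of normalized signal values, made by multiplying the counts of each library by 1 factor whose method is not stated, which was used only to compare its columns with the count files. Count totals per library ran from 7436442 to 25520050.

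Scn1a was examined first in every library. In the P24 129S6 libraries it went against the labels, and the file names of those 6 libraries give the opposite genotype to their titles and characteristics. Groups follow the titles and characteristics throughout, and those libraries are called labelled Scn1a+/- and labelled wild type.

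All counts were fitted with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) in 1 quasi-likelihood model with a coefficient for each of the 9 groups, TMM normalization and the filterByExpr filter (minimum count 10), which left 15912 genes. The common biological coefficient of variation was 7.57%, with 16 residual and 15.5 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Comparisons were Scn1a+/- minus wild type in each strain and age, the seizure group minus each of the other P24 F1 groups, F1 minus 129S6 at each age, and P24 minus P14 in each strain. Strain and age contrasts average the genotypes and leave out the seizure group. Differences of these differences were tested as interaction contrasts. Log2 fold changes carry an approximate standard error, the size of the fold change over the square root of its quasi-likelihood F statistic. Levels in CPM (counts scaled to the effective library size) carry the standard deviation over libraries. CPM values and fold changes were computed here from the deposited counts.

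The 33 gene lists were fixed before the data were examined: subunits of voltage-gated sodium, potassium and HCN, and calcium channels, GABA receptors and transporters, glutamate receptors, interneuron markers, activity-induced immediate early genes, seizure-responsive neuropeptides and late genes, astrocyte markers, reactive astrocyte genes, microglia markers, inflammatory cytokines and microglial activation, interferon-stimulated genes, myelin and mature oligodendrocyte genes, oligodendrocyte precursor genes, endothelial and pericyte markers, choroid plexus and ependymal markers, leptomeningeal and fibroblast markers, blood cell genes, thalamic and habenular, striatal and neocortical markers, dentate granule cell, CA1, and CA2 and CA3 markers, neurogenesis and cell cycle genes, cholesterol synthesis genes, heat shock and unfolded protein genes, glucocorticoid-responsive genes, candidate Dravet modifier genes, cytosolic ribosomal protein genes, oxidative phosphorylation genes, and sex-specific genes. Each list was tested with camera (preset correlation 0.01), adjusted over the lists of a comparison, and again with an estimated correlation and with fry, whose directional test asks whether a list moves on balance one way.

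Genes named in the text follow a rule fixed before the data were examined. It takes the 10 largest rises and 10 largest falls in genotype and seizure comparisons, and 5 of each in strain and age comparisons, among called genes with a mean log2 CPM of at least 0, no overlap between the libraries of the groups, and a symbol of a studied gene. It adds up to 4 called members of each list with the smallest adjusted p, or up to 2 members with the smallest p where none was called. Other genes named were chosen after their values were seen, and the text says so. Coordinates come from a RefSeq table of GRCm38.p6, the assembly of mm10. Of the symbols, 23204 matched that table's symbols, 1109 matched an older name only and 108 matched none. Exonic lengths came from GENCODE vM39 by symbol, for 97.9% of tested genes.

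The fitting steps were tested on simulated counts with 200 changed genes per comparison. At 1.5-fold, 65.7% of changed genes were recovered for the genotype comparison in P24 F1, 67.2% in P24 129S6, 74.6% in P14 F1 and 73.1% in P14 129S6, and 86.6% for the seizure group minus wild type. At 2-fold, 86.6% or more were recovered in each of these 5. The simulated groups all shared the same spread per gene, and only genes above a minimum mean count were changed. Recovery can therefore be lower in groups that vary more, such as the seizure group, at low counts, or where fewer genes change.

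Alternatives were relative log expression (RLE) normalization, DESeq2 1.42.0, no filter on low counts, a stricter filter, robust shrinkage, a fit of only the libraries compared, a 1.5-fold minimum, 1 genotype only for strain and age, the P24 129S6 genotype as file names write it, and each replicate left out. A fit without the seizure libraries was added, chosen after seeing the data. No pair of replicates was identical: over 23 pairs, the chi-square per degree of freedom between replicates ran from 2.42 to 40.2, with a median of 3.44. Its 3 highest values were the 3 pairs of seizure libraries.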

Results

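Gene expression was measured by RNA sequencing in the hippocampus of mice with 1 disrupted copy of Scn1a, a model of Dravet syndrome, and of wild-type mice. The series title sets a strain that resists seizures against one that is prone to them, and the F1 background is the one known for spontaneous seizures and early death. At P14 there were 3 Scn1a+/- and 2 wild-type 129S6 libraries, and 3 and 3 F1 libraries. At P24 there were 3 and 3 libraries as labelled in 129S6, and in F1 there were 2 Scn1a+/- libraries, 3 wild-type libraries and 3 libraries of Scn1a+/- mice with seizures. The seizure pools held 3 to 4 mice each and all other pools 12 to 16. Totals were 19553419 to 22026211 counts in the seizure group, 11606720 to 17813918 in the other P24 F1 Scn1a+/- libraries and 21816220 to 24011969 in P24 F1 wild type. Over all 25 libraries they ran from 7436442 to 25520050.

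Scn1a, which encodes the sodium channel subunit Nav1.1 (chromosome 2, 66270781 to 66440837, mm10), was the targeted gene and was read in every library. It stood at 98.1 ± 4.68 CPM (SD, n = 3) in P14 129S6 Scn1a+/- libraries against 111 ± 5.36 (n = 2) in wild type, and at 91.1 ± 1.33 (n = 3) against 103 ± 2.22 (n = 3) in P14 F1. In P24 F1 it was 127 ± 2.79 in wild type (n = 3), 104 ± 15.9 in Scn1a+/- (n = 2, with libraries at 115 and 92.9) and 79.9 ± 10.3 in the seizure group (n = 3). In the P24 129S6 libraries the order was the opposite of the labels: 140 ± 4.96 in libraries labelled Scn1a+/- and 110 ± 0.740 in those labelled wild type (n = 3 each). Every direction given for genotype in P24 129S6 therefore refers to labelled libraries only. By the column titles of the authors' deposited normalized table, the log2 ratio of Scn1a between P24 129S6 Scn1a+/- and wild type was -0.343. All 6 of those columns were proportional, within 0.1% over genes with at least 50 counts, to a count file of the other genotype, while the other 19 columns matched a count file of their own group.

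**Figure D1:**
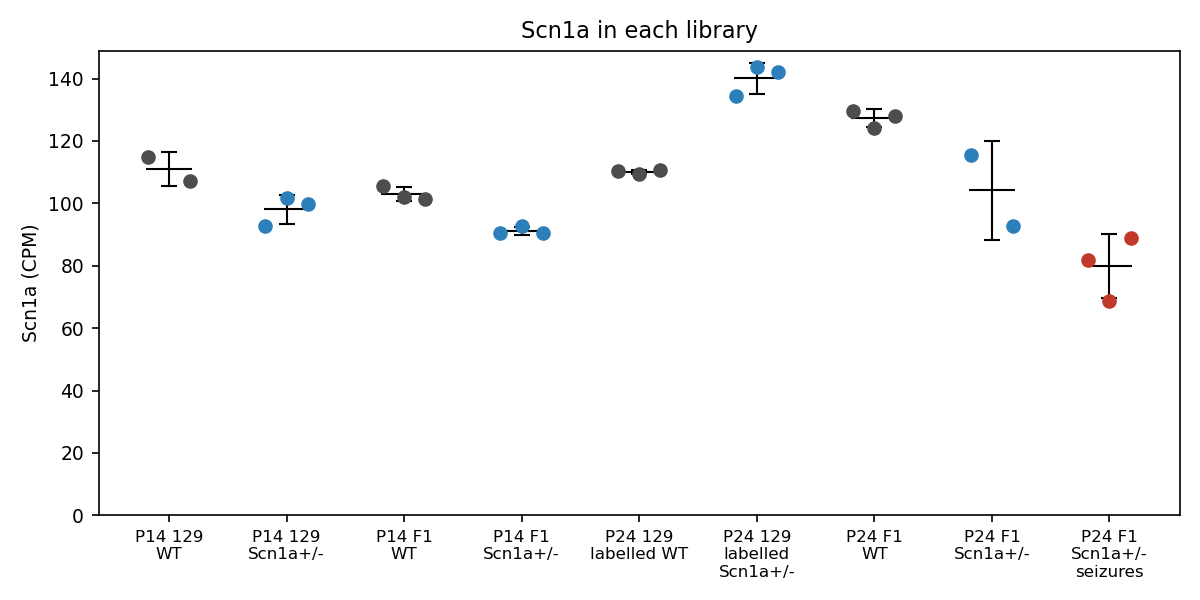
Scn1a in CPM for each of the 25 libraries (points) by group on the horizontal axis, with the group mean (long bar) and standard deviation (whiskers). Scn1a+/- libraries averaged below wild type in 3 of the 4 genotype pairs, and in P24 129S6 the libraries labelled Scn1a+/- averaged 140 against 110.

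The genotype comparisons ask what loss of 1 Scn1a copy does to the hippocampus without recorded seizures. At P14 the largest list members by p were small in size or low in level. In 129S6, Scn1a had a log2 fold change of -0.18 ± 0.08, Cacnb4, a calcium channel subunit, one of -0.16 ± 0.07, and Trh, a neuropeptide precursor, one of 4.01 ± 0.90 (edgeR adjusted p = 1 for each). In F1, Scn1a had -0.18 ± 0.08, Kcnh4, a potassium channel, -0.75 ± 0.25, and the complement gene C4b -0.45 ± 0.14 (edgeR adjusted p = 0.994 for each). No gene passed the edgeR test in 129S6 (0 of 15912) or in F1 (0), and DESeq2 also called 0 in each. At an unadjusted p under 0.05 there were 391 and 724 genes, fewer than the 796 expected by chance. The spread shared by all groups included the seizure libraries: the common biological coefficient of variation was 7.57% with them and 5.44% without. A fit without them also called 0 genes in each of these 2 comparisons. Adjusted over the list alone, 0 members passed in every list in F1, and in 129S6 only Trh, among the 30 measured seizure-responsive neuropeptides and late genes, did (list-wide adjusted p = 0.00283). Camera put 4 lists past its threshold in P14 129S6, glucocorticoid-responsive genes (median -0.12, adjusted p = 0.00424), oxidative phosphorylation genes (-0.06, 0.00525), glutamate receptors (0.06, 0.0346) and ribosomal protein genes (-0.07, 0.0377). Each had adjusted p = 0.832 with an estimated correlation, and in P14 F1 camera called 0 lists.

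In P24 F1, Scn1a+/- libraries without seizures had log2 fold changes against wild type of 1.39 ± 0.34 for Fosb, an activity-induced transcription factor, 0.46 ± 0.11 for Gfap, the astrocyte filament protein, and -0.29 ± 0.08 for Scn1a. The values were -0.51 ± 0.14 for the collagen gene Col1a2 and -0.48 ± 0.16 for Wfs1, a CA1 marker. None passed over all genes: edgeR called 0 (889 at an unadjusted p under 0.05 with 796 expected by chance, smallest adjusted p 0.833) and DESeq2 0. Adjusted over the list alone, 1 member passed in each of 5 lists: Scn1a (sodium channels), Fosb (immediate early genes), Gfap (reactive astrocyte genes), Col1a2 (leptomeningeal markers) and Xist, higher by 0.42 ± 0.15, among sex-specific genes. The sex-specific list served as a check of pool makeup, and whether the sex makeup of pools differed between groups was not tested. The 53 measured ribosomal protein genes had a median of 0.21, with Rpl7 at 0.35 ± 0.11 and Rps19 at 0.46 ± 0.16 (camera adjusted p = 3.83e-12), and the 59 oxidative phosphorylation genes one of 0.13 (2.31e-05). Over both lists the median was 0.17, but 0.06 without Scn1a+/- replicate 2 and 0.27 without replicate 1. Microglia markers (median 0.15) had 2.31e-05 as well. Of the 19 lists that passed camera, 6 were higher and 13 lower. The lower ones included potassium and HCN channels (median -0.10, 0.000287), CA1 markers (-0.13, 0.00499), leptomeningeal markers (-0.17, 0.00645), choroid plexus markers (-0.16, 0.00798) and thalamic and habenular markers (-0.16, 0.018). With an estimated correlation none of the 19 passed, with adjusted p = 0.528 for choroid plexus markers and adjusted p = 0.409 for the other 7 lists named here.

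Refitting without the 3 seizure libraries, an alternative chosen after seeing the data, edgeR called 200 genes in P24 F1 (92 higher, 108 lower). Of these, 177 went the opposite way in P14 129S6, 127 in P14 F1 and 176 in P24 129S6 by labels. With the genotype that the file names write for P24 129S6, those 176 went the same way as in P24 F1. Genes of a library can vary together, and P14 129S6 gave a count as uneven. These counts of direction therefore decide neither which labels are right nor whether the effect repeats. On the higher side, the 200 called genes included 4 of 47 immediate early genes, among them Fosb (1.40 ± 0.28), Npas4 (0.78 ± 0.17) and Fos (0.72 ± 0.18). Gfap (0.46 ± 0.08), Kcnj2 (0.61 ± 0.14) and 13 of 53 ribosomal protein genes were higher as well. Scn1a (-0.30 ± 0.06), Vgf (-0.54 ± 0.11) and Ttr (-0.56 ± 0.14) were on the lower side, and Npas4, Fos, Kcnj2 and Ttr were picked after their values were seen. These calls depend on which libraries are kept. The same fit called 0 genes without wild-type replicate 1, 72 without wild-type replicate 2 (70 shared with the 200) and 222 without wild-type replicate 3 (173 shared). Leaving out either Scn1a+/- replicate leaves 1 library, which the fit then assumes to vary like the other groups. The 2 Scn1a+/- libraries differed more than any replicate pair outside the seizure group (chi-square per degree of freedom 8.59). Whether the 200 calls hold in each of the 2 therefore cannot be tested. Fosb stood at 22.0 and 5.61 CPM in the 2 Scn1a+/- libraries and at 5.00 ± 0.657 in wild type (n = 3).

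In P24 129S6, Scn1a was higher in libraries labelled Scn1a+/- by 0.35 ± 0.08 (edgeR adjusted p = 0.414). Libraries labelled Scn1a+/- had Gfap at -0.22 ± 0.10, the choroid plexus genes Kl at 0.33 ± 0.11 and Enpp2 at 0.30 ± 0.13, and Fibcd1, a CA1 marker, at 0.26 ± 0.12. EdgeR called 0 genes (471 at an unadjusted p under 0.05, with 796 expected by chance) and DESeq2 0, and the edgeR fit without the seizure libraries called 2. Adjusted over the list alone, Scn1a passed among sodium channels (list-wide adjusted p = 0.000682) and Slc4a1, lower by labels at -1.97 ± 0.68, among 3 measured blood cell genes (0.0194). Camera called choroid plexus and ependymal markers (median 0.20, adjusted p = 0.000588) and CA1 markers (0.13, 0.00465), each with adjusted p = 0.972 with an estimated correlation.

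The seizure comparisons ask what accompanied seizures in F1 mice at P24. The first sets the seizure group against wild type, so its differences mix genotype and seizures, and the pools also differed in size. Penk, the enkephalin precursor (chromosome 4, 4133536 to 4138815), rose from 15.9 ± 1.58 to 264 ± 60.1 CPM (n = 3 each), a log2 fold change of 4.05 ± 0.14 (edgeR adjusted p = 1.63e-20). The 10 largest rises were Penk, Ifi202b (5.20 ± 0.49), the cytokine Lif (4.56 ± 0.45), the metalloproteinase inhibitor Timp1 (3.71 ± 0.21), Aldh1a3 (3.69 ± 0.30), the pentraxin Ptx3 (3.62 ± 0.31), Serpinf2 (3.54 ± 0.25), the activin subunit Inhba (3.48 ± 0.23), Wisp1 (3.45 ± 0.24) and Fosb (3.31 ± 0.29). The largest falls were in Tdo2, a tryptophan dioxygenase enriched in dentate granule cells (-2.79 ± 0.26, from 10.4 ± 1.25 to 1.47 ± 1.12 CPM), Zcchc5 (-2.65 ± 0.26), Nek10 (-2.19 ± 0.28), Plekhd1 (-1.89 ± 0.17), Otof (-1.84 ± 0.19), Cited4 (-1.81 ± 0.33), Fam160a1 (-1.81 ± 0.15), Catsperg1 (-1.69 ± 0.38), Rtp1 (-1.62 ± 0.28) and Alox12b (-1.55 ± 0.36). Scn1a itself was lower by -0.67 ± 0.07 (adjusted p = 2.67e-08). Of 15912 genes, 3579 were called, 1966 higher and 1613 lower in the seizure libraries, and 1043 of them changed at least 1.5-fold. Replicates of the seizure group differed most of all groups (chi-square per degree of freedom 18.3, 30.7 and 40.2 for its pairs), with Lif at 28.4 ± 27.2 CPM. A fit of only these libraries called 1615.

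**Figure D2:**
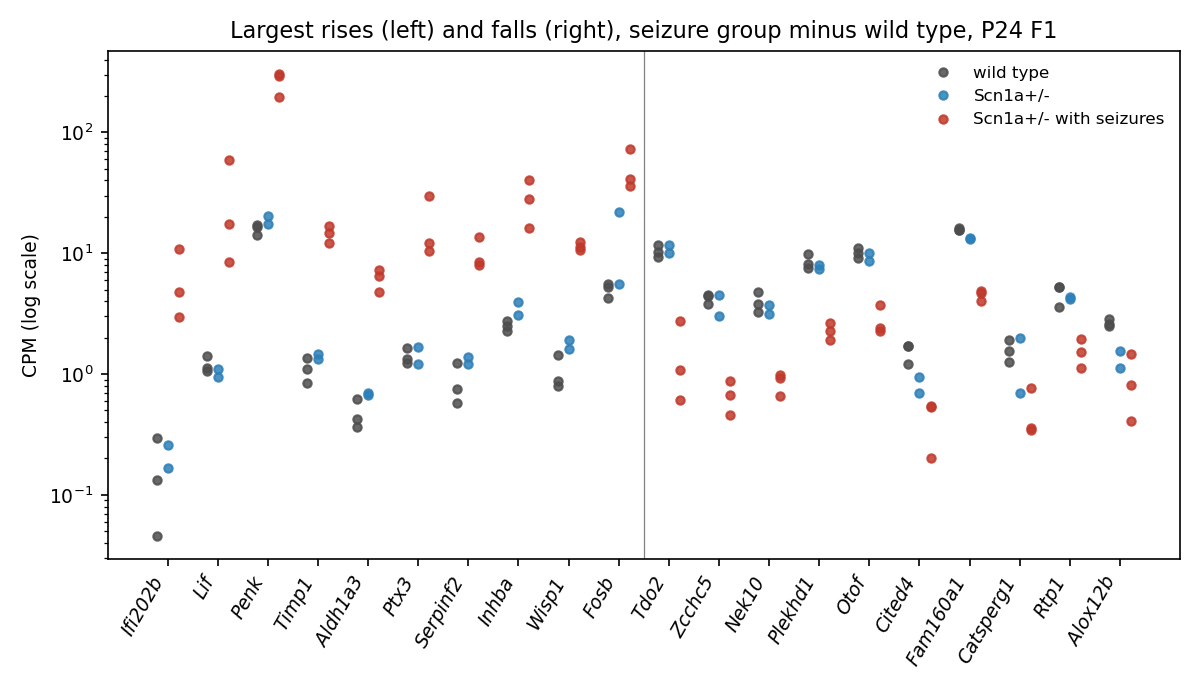
CPM on a log axis for the 10 largest rises and 10 largest falls between the seizure group and wild type, in each of the 8 P24 F1 libraries (1 point per library, colour by group). Penk averaged 264 in the seizure group and 15.9 in wild type. The 20 genes were chosen among those whose seizure and wild-type libraries do not overlap.

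Genes of glial reaction, neuronal activity and peptide signalling rose as groups. Of 34 measured reactive astrocyte genes, 23 rose and 2 fell (24 and 2 adjusted over the list alone), with the filament genes Gfap (2.31 ± 0.10, 587 ± 39.0 to 2918 ± 515 CPM) and Vim (2.12 ± 0.08) and the hyaluronan receptor Cd44 (3.29 ± 0.18). Camera gave an adjusted p of 1.21e-38 (0.000245 with an estimated correlation). Of 30 seizure-responsive neuropeptides and late genes, 21 rose and 1 fell (21 and 1 over the list alone), with Npy, neuropeptide Y (1.88 ± 0.10), and the activin receptor Acvr1c (2.14 ± 0.12) after Penk. Camera gave 2.12e-31 (0.00214 with an estimated correlation). Of 47 immediate early genes, 32 rose and 1 fell (33 and 3 over the list alone), among them Fos (2.43 ± 0.19), Rgs2 (1.60 ± 0.10), Ier5 (1.52 ± 0.12) and Klf10 (1.46 ± 0.12). Camera gave 1.02e-20 (0.0427 with an estimated correlation). Of 21 inflammatory genes, 9 rose and 2 fell (10 and 2 over the list alone), led by Gpnmb (2.63 ± 0.20), Socs3 (3.06 ± 0.30) and Hmox1 (1.37 ± 0.18). Camera gave 4.13e-05 (0.0122 with an estimated correlation). Of 25 cholesterol synthesis genes, 19 rose and 0 fell (21 and 0 over the list alone), with Msmo1 (0.72 ± 0.06), Sqle (0.72 ± 0.07) and Hmgcs1 (0.60 ± 0.06). Camera gave 2.43e-15 (0.000714 with an estimated correlation). Of 34 neurogenesis and cell cycle genes, 12 rose and 0 fell (13 and 0 over the list alone), with the immature-neuron genes Sox11 (1.13 ± 0.09), Tubb2b (0.98 ± 0.08) and Igfbpl1 (1.03 ± 0.10). Camera gave 2.65e-05 (0.0122 with an estimated correlation). These 6 were the lists whose camera call held with an estimated correlation.

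**Figure D3:**
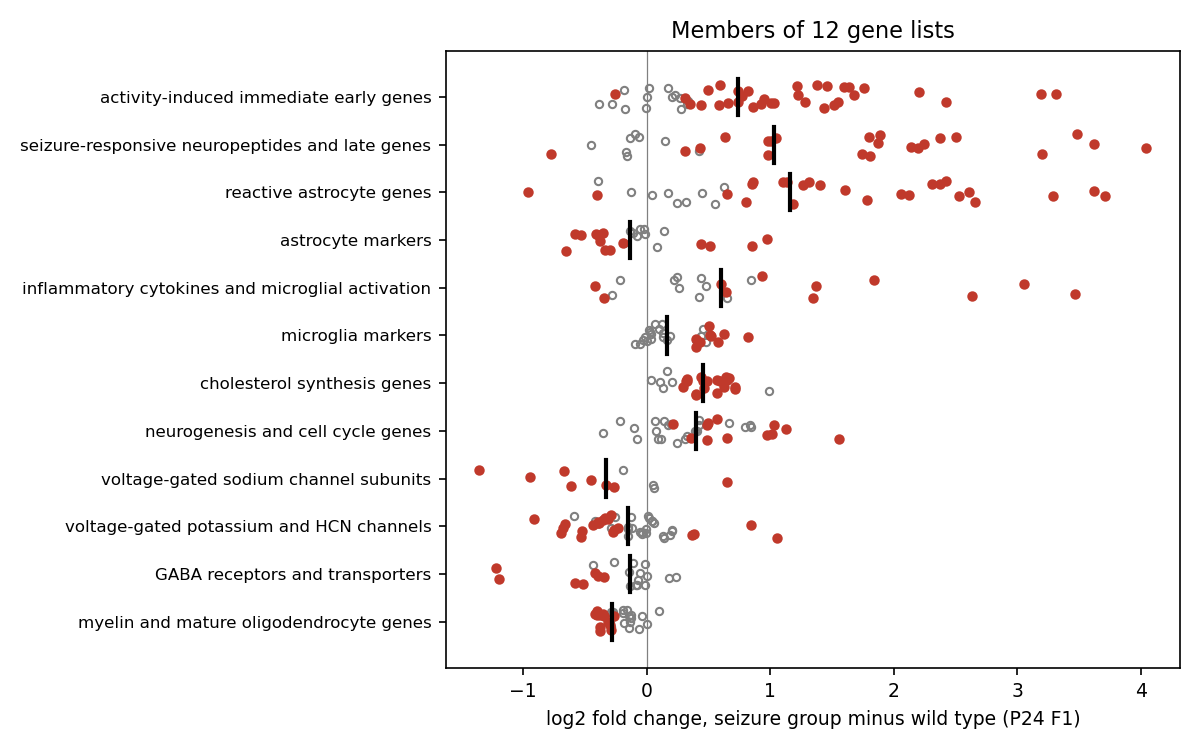
Log2 fold change between the seizure group and wild type (horizontal axis) of each measured member of 12 gene lists (1 point per gene, filled where the edgeR adjusted p is under 0.05), with the list median as a bar. The median was 1.16 for reactive astrocyte genes and -0.33 for sodium channel subunits.

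Ion channel and receptor genes were lower more often than higher. Of 11 sodium channel subunits, 7 fell and 1 rose (8 and 1 adjusted over the list alone), with Scn4b (-1.35 ± 0.13), Scn3b (-0.61 ± 0.09) and Scn2b (-0.45 ± 0.08) beside Scn1a. Camera gave an adjusted p of 1.28e-05 (adjusted p = 0.0885 with an estimated correlation). Of 21 GABA receptor and transporter genes, 7 fell and 0 rose (8 and 2 over the list alone), with Gabrd, a subunit of extrasynaptic GABA receptors (-1.22 ± 0.10), the transporter Slc6a13 (-1.19 ± 0.18) and the GABA-degrading enzyme Abat (-0.40 ± 0.06). Camera gave 6.22e-05 (adjusted p = 0.0894 with an estimated correlation). Of 45 potassium and HCN channel genes, 17 fell and 4 rose (17 and 4 over the list alone): Kcnip2 (-0.68 ± 0.06), Kcnq3 (-0.53 ± 0.07) and Kcnh7 (-0.91 ± 0.14) fell while Kcnip3 (1.05 ± 0.09) rose. Camera gave 0.000895 (adjusted p = 0.397 with an estimated correlation). Of 25 glutamate receptors, 9 fell and 2 rose (10 and 3 over the list alone), with Gria2 (-0.34 ± 0.06) and Grik3 (-0.54 ± 0.09). Camera gave 0.043 (adjusted p = 0.464 with an estimated correlation). Of 22 calcium channel subunits, 5 fell and 2 rose (7 and 2 over the list alone), and the 2 were the T-type channel Cacna1g (0.98 ± 0.07) and Cacna2d2 (1.46 ± 0.13), with camera at 0.8. Of 14 candidate Dravet modifier genes, 4 fell and 2 rose (5 and 2 over the list alone), led by the transcription factor Hlf (-1.18 ± 0.07) and Cacna1g, with camera at 0.133.

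Of 19 dentate granule cell markers, 8 fell and 4 rose (8 and 4 adjusted over the list alone), with Dsp (-1.45 ± 0.12) and Lct (-1.44 ± 0.17) lower and Gsg1l (1.18 ± 0.14) higher (camera adjusted p = 0.0044, and adjusted p = 0.0885 with an estimated correlation). Of 15 CA1 markers, 6 fell and 0 rose (7 and 0 over the list alone), with Fibcd1 (-1.06 ± 0.12) and Itpka (-0.48 ± 0.06) (0.00128, and adjusted p = 0.247 with an estimated correlation). Of 21 CA2 and CA3 markers, 6 rose and 1 fell (7 and 3 over the list alone), with Grik4 (0.29 ± 0.07) higher and Cpne4 (-0.38 ± 0.10) lower, at 0.96. Of 30 interneuron markers, 5 rose and 3 fell (5 and 3 over the list alone), with Calb2 (0.67 ± 0.09) and Gad2 (0.40 ± 0.09) higher and Lamp5 (-0.98 ± 0.10) lower, at 0.8. Among markers of neighbouring regions, 8 of 20 neocortical genes fell and 1, Rprm (1.87 ± 0.11), rose (9 and 1 over the list alone). Camera gave 0.022 (adjusted p = 0.248 with an estimated correlation). Of 21 thalamic and habenular markers, 6 fell and 3 rose (8 and 3 over the list alone), Calb2 among the rises, at 0.189. Of 15 striatal markers, 4 rose and 2 fell (4 and 2 over the list alone), with the dopamine receptor Drd1 (2.02 ± 0.16) higher, at 0.309.

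Among glial, vascular and other lists, 10 of 23 astrocyte markers fell and 4 rose (10 and 4 adjusted over the list alone), with glutamine synthetase, Glul (-0.58 ± 0.06), lower and the water channel Aqp4 (0.98 ± 0.07) higher (camera adjusted p = 0.022, and adjusted p = 0.464 with an estimated correlation). Of 30 myelin genes, 12 fell and 0 rose (14 and 0 over the list alone), with Cnp (-0.40 ± 0.09) and Mal (-0.42 ± 0.10). Of 29 microglia markers, 9 rose and 0 fell (10 and 0 over the list alone), with the complement gene C1qb (0.63 ± 0.10). Camera gave 4.13e-05 for myelin and 0.00309 for microglia, each with adjusted p = 0.397 with an estimated correlation. Of 24 glucocorticoid-responsive genes, 12 fell and 3 rose (12 and 3 over the list alone), with Tsc22d3 (-0.76 ± 0.08) lower and the cell cycle inhibitor Cdkn1a (1.46 ± 0.14) higher. Of 30 heat shock genes, 14 rose and 0 fell (14 and 0 over the list alone), with Bag3 (1.41 ± 0.17) and Hspb1 (2.37 ± 0.31). Both passed camera, at 6.88e-05 and 8.9e-06, each with adjusted p = 0.0894 with an estimated correlation. Of 53 ribosomal protein genes, 22 rose (32 over the list alone, with Rplp0 at 0.47 ± 0.10). Of 59 oxidative phosphorylation genes, 23 rose (27 over the list alone, with Uqcrq at 0.40 ± 0.08). None of either list fell, and camera gave 2.82e-05 and 6.37e-05, each with adjusted p = 0.397 with an estimated correlation. Many ribosomal protein genes share reads with near-identical copies, so their counts are uncertain.

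The remaining lists did not pass camera against wild type. Leptomeningeal and fibroblast markers split, with Col3a1 (1.39 ± 0.13) and Bgn (1.40 ± 0.12) among 3 of 19 that rose and Fmod (-1.35 ± 0.17) among 8 that fell (4 and 8 adjusted over the list alone, camera adjusted p = 0.148). Of 27 endothelial and pericyte markers, 7 fell and 3 rose (7 and 4 over the list alone), with Rgs5 at 0.31 ± 0.07 and Slco1a4 at -0.38 ± 0.09 (0.411). Of 23 choroid plexus and ependymal markers, 2 rose and 1 fell (2 and 1 over the list alone), with Prlr at 1.21 ± 0.17 (0.911). Of 17 oligodendrocyte precursor genes, 2 rose and 3 fell (2 and 3 over the list alone), with Emid1 at 0.51 ± 0.10 (0.907). Of 26 interferon-stimulated genes, 3 rose (2 over the list alone), led by Ifitm3 (1.24 ± 0.17), and 0 fell (0.141). None of 3 measured blood cell genes passed the edgeR test (1, S100a9 at 1.34 ± 0.50, over the list alone, and 0.911). Of 5 sex-specific genes, Eif2s3y on the Y chromosome was lower (-0.38 ± 0.11, edgeR adjusted p = 0.00833, 1 over the list alone), with the list at 0.206. Median and mean of the members differed in sign for calcium channels, interneuron, striatal, CA2 and CA3, oligodendrocyte precursor and blood cell genes.

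Against the Scn1a+/- libraries without seizures (n = 2), Penk rose in the seizure group by 3.81 ± 0.16 from 18.9 ± 2.12 CPM (edgeR adjusted p = 2.57e-17), with Ifi202b (4.87 ± 0.62), Lif (4.75 ± 0.58), Ptx3 (3.56 ± 0.39), Wnt9b (3.40 ± 0.53), Timp1 (3.38 ± 0.25), Mybpc3 (3.34 ± 0.82), Sdc1 (3.31 ± 0.38) and Bmp3 (3.23 ± 0.29). Tdo2 (-2.83 ± 0.28), Zcchc5 (-2.44 ± 0.30), Nek10 (-1.98 ± 0.32), Clca3a1 (-1.79 ± 0.58) and Plekhd1 (-1.76 ± 0.20) had the largest falls, and Otof, Atp6v1c2, Actrt3, BC030499 and Tbc1d10c fell by 1.61 or more. Scn1a was lower, at -0.38 ± 0.08 (adjusted p = 0.00164). Of 34 reactive astrocyte genes, 22 rose and 0 fell (23 and 0 adjusted over the list alone, Gfap 1.86 ± 0.12), of 30 neuropeptides and late genes 20 rose and 1 fell (22 and 3, Nptx2 2.80 ± 0.25). Of 47 immediate early genes, 30 rose and 0 fell (32 and 0, Gadd45b 1.62 ± 0.18), of 25 cholesterol synthesis genes 19 rose and 0 fell (21 and 0, Fdft1 0.76 ± 0.09). Of 21 inflammatory genes, 7 rose and 1 fell (7 and 2, Ccl12 3.21 ± 0.61). Of 30 heat shock genes, 12 rose and 0 fell (14 and 0, Hsph1 0.85 ± 0.11). Camera's adjusted p with an estimated correlation was 0.000489 for reactive astrocyte genes, 0.00203 for neuropeptides, 0.000489 for cholesterol synthesis, 0.0197 for inflammatory and 0.0463 for heat shock genes. For immediate early genes the preset value was 2.7e-18, with adjusted p = 0.0519 with an estimated correlation. Of 34 neurogenesis and cell cycle genes, 7 rose and 0 fell (7 and 0, camera 0.0021, and adjusted p = 0.0537 with an estimated correlation). Of 11 sodium channel subunits, 6 fell and 1 rose (6 and 2), Scn9a (-1.26 ± 0.21) and Scn4b (-0.98 ± 0.15) among the falls (camera 0.000688, and adjusted p = 0.204 with an estimated correlation). None of 53 ribosomal protein genes passed, also over the list alone, and 2 of 59 oxidative phosphorylation genes rose (1 over the list alone). In all, edgeR called 2502 genes (1388 higher, 1114 lower), 903 of them changed at least 1.5-fold. The count was 1519 without Scn1a+/- replicate 2, and 633 in a fit of only these libraries.

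The strain comparisons ask which genes differ between F1 and 129S6 whatever the genotype. Several of the largest differences were in genes with near-identical copies: Rps3a1 (4.22 ± 0.17 at P14, 4.17 ± 0.16 at P24), Rpl29 (4.03 ± 0.24 and 4.08 ± 0.24) and Rpl3 (3.45 ± 0.16 and 3.59 ± 0.15) were higher in F1. Hspa8, another gene with such copies, was higher by less (1.55 ± 0.09 at each age). Reads were aligned to mm10, a C57BL/6J reference, so 129S6 sequence differences can lower counts and these values are uncertain. Other large rises were Krt12 (3.55 ± 0.21 and 4.26 ± 0.22), Oscar at P14 (3.09 ± 0.46) and the securin gene Pttg1 at P24 (3.74 ± 0.17). Klk1b22 (-2.58 ± 0.39 at P14, -2.41 ± 0.32 at P24) had the largest fall, followed by Sycp1, Tmprss11a, Tmem72 and Dapk2 at P14 (-1.42 to -1.28) and Gdpd3, Rps15a-ps6, Serpina3m and Stbd1 at P24 (-1.36 to -1.16). EdgeR called 588 genes at P14 (324 higher, 264 lower in F1) and 1008 at P24 (551 and 457). Of these, 225 were higher at both ages (11.2 expected by chance for independent lists) and 135 lower at both (7.58 expected), with 0 called in opposite directions. Sequence differences from the reference can shift the same genes at both ages, so the overlap does not separate expression from alignment. The same holds for single genes that differed at both ages.

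Gabra2, a GABA receptor subunit among the candidate Dravet modifier genes (chromosome 5, 70958392 to 71095849), was lower in F1 at both ages, by -0.57 ± 0.06 at P14 (125 ± 6.49 against 188 ± 8.85 CPM, n = 6 and 5, edgeR adjusted p = 1.3e-08) and -0.64 ± 0.06 at P24 (1.15e-09). Clcn6, a chloride transporter gene and the other called member of the 14 candidate modifiers, was lower by -0.28 ± 0.06 and -0.27 ± 0.06 (camera adjusted p = 0.0644 and 0.172 for the list). Microglia markers were higher in F1, 6 of 29 at P14 and 12 at P24 (10 and 18 adjusted over the list alone), with Olfml3 (1.95 ± 0.14 and 1.78 ± 0.14), Fcrls (1.22 ± 0.09 and 1.57 ± 0.10), the perforin-like Mpeg1 (1.26 ± 0.12 and 1.25 ± 0.10) and Ly86 (0.75 ± 0.12 and 0.77 ± 0.12). Camera gave 3.47e-16 and 4.64e-20, with adjusted p = 0.0992 and 0.1 with an estimated correlation. At P14, 8 of 19 leptomeningeal markers were lower in F1 (11 over the list alone), Igf2 (-0.85 ± 0.09) and Ogn (-0.82 ± 0.14) among them (3.01e-10, and 0.00675 with an estimated correlation), and 7 of 23 choroid plexus markers (13 over the list alone), Prlr (-0.70 ± 0.16) and Kcne2 (-0.77 ± 0.19) among them (1.37e-07, and adjusted p = 0.478 with an estimated correlation). At P24, 3 leptomeningeal markers were lower and 1 higher (4 and 1 over the list alone), and 2 choroid plexus markers, Ttr (-0.66 ± 0.15) and Clic6 (-0.58 ± 0.16), were lower and 1 higher (5 and 2 over the list alone), neither list past camera with an estimated correlation (adjusted p = 0.69 and 0.895). Among neuron genes that differed at both ages were the potassium channel gene Kcns1 (1.18 ± 0.16 and 0.68 ± 0.15), the serotonin receptor Htr3a (0.98 ± 0.16 and 1.05 ± 0.14), the CA1 marker Spink8 (1.04 ± 0.14 and 0.74 ± 0.12) and Iyd (1.82 ± 0.19 and 1.21 ± 0.17), all higher in F1. Of 45 potassium and HCN channels, 2 were higher and 1 lower at P14 (2 and 1 over the list alone), and 3 higher and 5 lower at P24 (4 and 5). Of 30 interneuron markers, 3 were higher and 1 lower at P14 (3 and 1), and 1 higher and 2 lower at P24 (1 and 4). Of 21 GABA receptor and transporter genes, 0 were higher and 2 lower at P14 (1 and 2), and 0 higher and 3 lower at P24 (0 and 4). Of 34 reactive astrocyte genes, 2 were higher and 1 lower at P14 (2 and 2), and 0 higher and 2 lower at P24 (2 and 2), Serpina3n lower at both ages (-0.72 ± 0.06 and -0.77 ± 0.06). No sodium channel subunit, glutamate receptor or immediate early gene was called at either age by edgeR. Without P24 F1 Scn1a+/- replicate 2, the count at P24 was 423, and without P14 129S6 wild-type replicate 2 that at P14 was 380.

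The age comparisons ask what changes between P14 and P24 in each strain. Myelin genes rose: 28 of 30 in F1 and 28 in 129S6 (28 and 28 adjusted over the list alone), with the myelin proteolipid gene Mal (2.43 ± 0.08 in F1, 2.44 ± 0.08 in 129S6) and Hapln2, a protein of nodes of Ranvier (3.62 ± 0.16 and 3.08 ± 0.16). Genes of neurogenesis and the cell cycle fell, 31 of 34 in F1 and 34 in 129S6 (32 and 34 over the list alone), with Dpysl3 (-1.67 ± 0.06 and -1.53 ± 0.06), Dcx (-1.33 ± 0.06 and -1.35 ± 0.06) and the mitotic genes Aurkb (-2.49 ± 0.31 and -2.39 ± 0.34) and Hmmr (-2.13 ± 0.24 and -2.60 ± 0.26). Oligodendrocyte precursor genes fell, 15 of 17 in each strain (15 over the list alone), with Emid1 (-1.48 ± 0.08 and -1.38 ± 0.08) and Gpr17 (-0.84 ± 0.06 and -0.97 ± 0.05), as did 18 and 19 of 25 cholesterol synthesis genes (18 and 19 over the list alone), with Hmgcs1 (-0.76 ± 0.05 and -0.70 ± 0.05) and 1 member higher in each strain. These 4 lists passed camera with an estimated correlation, at 0.000855 and 0.000769 for myelin, 6.96e-07 and 7.45e-07 for neurogenesis, 0.00158 and 0.000406 for precursor genes and 0.0106 and 0.0118 for cholesterol synthesis.

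The largest other rises were Sspo (3.00 ± 0.18 and 2.66 ± 0.18), Tmprss6 (2.85 ± 0.33) and Etnppl (2.45 ± 0.21) in F1 and Tnfaip6 (3.30 ± 0.20) and Cyp2j12 (2.72 ± 0.27) in 129S6. The largest other falls were the apelin receptor Aplnr (-3.12 ± 0.19 and -3.49 ± 0.19), the fetal RNA H19 (-2.27 ± 0.24 and -3.12 ± 0.23), Pcdh12 (-2.60 ± 0.29) in F1 and Bub1b (-2.40 ± 0.23) in 129S6. Dentate granule cell markers rose in part, 12 of 19 in each strain with 1 and 3 lower, Dsp (0.70 ± 0.09 and 0.66 ± 0.09) among the rises (camera adjusted p = 0.00373 and 0.00459, and adjusted p = 0.0832 and 0.0899 with an estimated correlation). Of 24 glucocorticoid-responsive genes, 15 rose in each strain and 2 and 3 fell, with Sgk1 (0.81 ± 0.07 and 0.87 ± 0.07) (0.000793 and 0.000328, and adjusted p = 0.243 and 0.142 with an estimated correlation). Endothelial and pericyte markers fell more often than they rose, 12 against 4 of 27 in F1 and 14 against 4 in 129S6, with the pericyte gene Rgs5 (-1.04 ± 0.05 in F1) and the tight junction gene Cldn5 (-0.93 ± 0.08 and -1.01 ± 0.08) (0.00334 and 0.000168, and adjusted p = 0.5 and 0.216 with an estimated correlation). Oxidative phosphorylation genes fell, 36 of 59 in F1 and 27 in 129S6 with 1 higher (7.57e-07 and 2.52e-05, and adjusted p = 0.5 and 0.53 with an estimated correlation). Single channel and receptor genes followed age in both strains: Scn1a rose by 0.25 ± 0.06 in each (edgeR adjusted p = 0.00083 and 0.000771), the potassium channel Kcna1 by 0.53 ± 0.06 in each, and the NMDA receptor subunit Grin2a by 0.75 ± 0.07 and 0.57 ± 0.07, while Grin3a fell (-0.72 ± 0.07 and -0.48 ± 0.07). Parvalbumin, Pvalb, rose (0.70 ± 0.08 and 0.67 ± 0.08). EdgeR called 6107 genes in F1 (3024 higher, 3083 lower at P24) and 5459 in 129S6 (2745 and 2714). Of these, 2014 were higher in both strains (522 expected for independent lists), 2071 lower in both (526 expected), and 1 was higher in F1 and lower in 129S6. In 129S6 the rise of Scn1a with age was not seen in libraries labelled wild type alone (-0.01, adjusted p = 0.95).

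Differences between effects were tested as interactions. The genotype effect on Scn1a differed between strains at P24 by -0.64 ± 0.11 (edgeR adjusted p = 0.0473), the 1 gene called. With the genotype of P24 129S6 as the file names write it, the difference was 0.05 and edgeR called 0 genes. It also called 0 with RLE normalization and in 10 of the 11 fits that left out 1 library, with 1 gene only without F1 Scn1a+/- replicate 1. The count was 10 with no filter on low counts, 60 in a fit of only these libraries and 137 in the fit without the seizure libraries (1 there with the file-name genotype). The genotype effects differed between strains at P14 for 0 genes (495 at an unadjusted p under 0.05), between ages in F1 for 0 (804) and between ages in 129S6, by labels, for 0 (383), and DESeq2 also called 0 in these 3. By chance 796 genes would be under 0.05 in each. The strain effect differed between ages for 1 gene, the mitotic checkpoint kinase Bub1b (chromosome 2, 118598202 to 118641592), by 2.17 ± 0.28 (adjusted p = 0.000125). Bub1b averaged 0.422 CPM in P24 129S6 libraries labelled Scn1a+/- and 0.432 in those labelled wild type, 2.81 and 3.59 in the P24 F1 groups, and 2.04 to 3.87 in the P14 groups. DESeq2 called 2 genes for this difference. EdgeR called 6 with no filter on low counts, and 42 both in a fit of only these libraries and in the fit without the seizure libraries.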

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

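The tests of exchanged columns and of Scn1a by the authors' table titles, of one even share of seizure tissue, of 1 library that stands apart, and of ribosomal and oxidative phosphorylation genes in P14 F1 were chosen only after the result was seen.

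The genotype effect on Scn1a at P24 differed between F1 and 129S6 by -0.64 in log2, a difference between groups, because Scn1a was higher in the P24 129S6 libraries labelled Scn1a+/-. All 6 columns that the authors' normalized table titles P24 129S6 were proportional to a count file of the other genotype, a signal in data that the comparisons did not use. An exchange of the count files between the P24 129S6 sample records is a candidate explanation, since it needs all 6 columns to be exchanged and 6 were. By the titles of that table the log2 ratio of Scn1a was -0.343, the file names of the same 6 libraries also give the opposite genotype to their labels, and Scn1a averaged lower in Scn1a+/- than in wild type in the other 3 genotype pairs. The table titles and the sample labels give the same counts opposite genotypes, so both cannot be right. A rise of Scn1a with the genotype in P24 129S6 needs the table titles and the file names to be wrong. These values go with wrong sample labels and argue against such a rise. They do not settle it, because titles and file names may share 1 origin and the other pairs are other mice.

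The strain effect on Bub1b differed between ages by 2.17 in log2, also a difference between groups. No technical or biological explanation for it was tested.

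Over 439 genes called and at least 2-fold apart between the seizure libraries and the P24 129S6 libraries and had an unadjusted p of at least 0.05 for strain at P14, the P24 F1 Scn1a+/- libraries without seizures had a median log2 difference from wild type, signed by the seizure direction, of 0.0749. Both libraries scored above all 3 wild-type libraries (0.0552 and 0.0336 against at most 0.0119), but 2 against 3 libraries make 10 splits, too few for a share under 0.05. On the same scale the seizure libraries scored 0.769 to 1.05. The P14 libraries of both strains and genotypes scored 0.053 to 0.104, so scores of this size are not particular to seizures. A gene length trend is argued against as the whole cause, since the signed median was 0.0702 after its removal, and an effect already present in F1 at P14 is argued against by a signed median of 0.0152 there. One even share of seizure tissue in the Scn1a+/- pools is not settled: the shares that 291 genes imply varied more than their errors (heterogeneity 1.38 per degree of freedom, chi-square p = 1.58e-05), with a weighted mean of 0.855% and a median of 3.65%, but those errors leave out that of the seizure fold changes and treat genes as independent. An effect of genotype that appears by P24, or seizures that were not seen in these mice, would need other data and stay open.

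Ribosomal protein and oxidative phosphorylation genes were higher in the P24 F1 Scn1a+/- libraries than in wild type, with a median log2 difference of 0.175 over 112 genes. An effect also present in F1 at P14 is argued against by a median of -0.0199 there. Without Scn1a+/- replicate 2 the median was 0.0638, so 1 library that stands apart may account for much of it. After removing the gene length trend the median was 0.137, and a part from that trend and a difference of genotype cannot be told apart with 2 libraries.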

How the results depend on the processing

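The tests without the seizure libraries were chosen after seeing the data, and the other alternatives were set before the data were examined. Scn1a in the difference of genotype effects between strains at P24 changed direction with the genotype as the file names write it (0.0545, 0 genes), also without the seizure libraries (0.0490, 1 gene, Btg2), and its change with age in 129S6 did so in libraries labelled wild type alone (-0.0115), where the P24 labels decide. With no filter on low counts, genotype counts were 4 (P14 129S6), 3 (P24 129S6) and 9 (P24 F1). The difference of genotype effects then gave 10 between strains at P24 and 1 between ages in 129S6, and the strain by age difference gave 6. DESeq2 gave 2 for strain by age, and its scaling 0 for genotype by strain at P24. Fits of only the libraries compared gave 1 (genotype P14 F1), 2 (P24 129S6), 3 (P24 F1), 1615 (seizure against wild type), 633 (against Scn1a+/-), 1051 and 1950 (strain, P14 and P24). They also gave 60 (genotype by strain P24), 2 and 1 (genotype by age, F1 and 129S6) and 42 (strain by age). A fold minimum of 1.5 gave 1043 and 903 for the seizure comparisons. Libraries labelled wild type alone gave 179 and 488 (strain) and 2833 (age 129S6). Scn1a+/- libraries alone gave 228, 272, 3468 (age F1) and 3634 (age 129S6), with fewer samples. Without the seizure libraries, counts were 2 (genotype P24 129S6), 200 (P24 F1), 991 and 2104 (strain), 137 (genotype by strain P24, and 1 with the file-name genotype), 5 and 1 (genotype by age) and 42 (strain by age). Lists past camera went with an estimated correlation from 4 to 0 (genotype P14 129S6), 2 to 0 (P24 129S6), 19 to 0 (P24 F1), 20 to 6 and 13 to 5 (seizure), 6 to 1 and 5 to 0 (strain), and 11 to 4 and 16 to 4 (age). Fry gave 3 and 3 for strain and 0 for those genotype comparisons. Leaving out each library gave 2640 to 4751 (seizure against wild type), 1519 to 2964 (against Scn1a+/-). For strain it gave 380 to 543 and 423 to 1360, and for age 5001 to 5879 and 4386 to 5206. It gave 0 to 4 (genotype P24 F1, and 0 to 561 without the seizure libraries, where leaving out wild-type replicate 2 or 3 gave 72 or 222), 0 to 1 (genotype P24 129S6 and genotype by strain P24) and 1 to 3 (strain by age). Fits of only the libraries compared lowered the seizure counts but raised the strain counts, so fewer samples alone do not account for both. The seizure replicates differed most of all groups, and the spread shared by all groups included them. The common biological coefficient of variation was 7.57% with the seizure libraries and 5.44% without. For the other alternatives, except where fewer samples or genes were used, the cause was not tested. Among named genes called, 105 of 135 (seizure against wild type), 73 of 122 (against Scn1a+/-), 22 of 57 and 30 of 74 (strain), and 114 of 132 and 112 of 132 (age) kept their call in every alternative. No paired analysis was possible because the labels give no replicate numbers shared across groups (title numbers run over the series).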

Other observations

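The tests of overlap between seizure and age genes were chosen only after the result was seen.

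Genes that change with age in 129S6 may be set back toward P14 in the seizure libraries, a hypothesis. Over 5459 genes the mean maturation score of the 3 seizure libraries was below that of the other 5 P24 F1 libraries by a difference of -0.0959 (exact permutation p = 0.0179, the smallest that 56 splits can give), against an age difference of 0.359 in F1. Genes higher in the seizure libraries than in wild type and lower with age numbered 645 (335 expected for independent lists), and those lower and higher with age 644 (278 expected). Genes that moved the same way in both numbered 217 higher (339 expected) and 217 lower (275 expected).

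Other splits of the same libraries were counted where each group had at least 3. The strain, age and strain by age splits used fits of only the libraries compared, so their real counts are not those of the report, which come from the fit of all 25 libraries, as do the seizure and genotype splits. For strain, 1 of 100 splits, the real one, gave as many genes at P14 (1051, highest other 514) and at P24 (1950, highest other 558). For age, 1 of 100 did in F1 (7018, highest other 4175) and 1 of 100 in 129S6 (6425, highest other 3832). In each of these the real split called more genes than every other split tried. A share of 1 of 100 is the smallest that 100 splits can give. Splits cannot test a difference of litter or day that goes with strain or age. For the strain by age difference, 3 of 100 splits gave as many genes (42, highest other 510). Other splits can carry the strain or age differences of the libraries into the tested difference. Their counts therefore cannot decide whether chance gives the 42 genes. For seizure against wild type, 1 of 10 splits gave as many (3579, highest other 598), and for genotype in P14 F1 and P24 129S6 10 of 10 did (0, highest other 0), where 10 splits are too few for a share under 0.05.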
